A study of Dehalococcoides mccartyi with 6 samples.

How the data were processed

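RNA of Dehalococcoides ethenogenes strain 195, measured inside the mixed dechlorinating culture called Donna II, was hybridised to 6 custom Agilent arrays with 2 dyes each. Per the labels, strain 195 made up about 60% of the cells, next to fermenters and methanogens. The arrays held 2 continuous PCE cultures, each in Cy3 with the batch PCE control in Cy5, and 2 continuous TCE cultures, each in Cy5 with the control in Cy3. A further array set TCE (Cy5) directly against PCE (Cy3) and the last set the batch control against itself. The series text calls the direct array a technical replicate and names 2 biological replicates per feeding. The direct array holds RNA of cultures that are also on other arrays and adds no culture. The growth text in the labels also speaks of a pool starved for 3 days as a common Cy3 control, whereas the channel labels and the series text name the 6 h batch PCE culture. The channel labels were followed.

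The deposited scanner files hold spot and local background intensity in both channels, extracted with Agilent Feature Extraction 10.1.1.1 per the file headers, while the submitters' processing notes name version 10.5. The files also carry processed signal intensity, from which Feature Extraction had subtracted background and which it had normalised between dyes, and the log10 ratio of Cy5 over Cy3 derived from it, per the file headers and column names. The authors' deposited value table holds log10 ratios that equal the scanner log10 ratios within 0.005. Its columns for continuous PCE replicates 1 and 2 are exchanged relative to the scanner files, and the other 4 columns match their own arrays. All 6 columns have a median of 0, and scale and direction follow from the match. Sample groups, dyes and directions were taken from the labels and not from values.

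The design fixed beforehand named the mean spot signal, but the files used here give the median spot signal, so the median was used. Background was corrected with normexp (offset 50) from the spot median and local background median. Spots flagged as outliers by Feature Extraction were left out (2.29% to 4.06% of the 15208 probe spots per array). Log ratios were normalised within each array by loess fitted on strain 195 probes. Of 1526 strain 195 probes, 48 were left out because they were not well above background in either channel on at least 2 of the 6 arrays, with a probe counted as above background on an array when at least a share of 0.5 of its spots was. Spots of a probe (5 to 15 per probe) were averaged, and the 13 genes with 2 probes were averaged over them. Those probes differed by at most 0.16 log2 units on any array. This left 1465 of 1513 genes. Fold changes of dim genes are drawn towards 0 by the offset. Of all called genes, 1 was not well above background in any array of a group; it is not named.

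Each gene was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes). The model had a coefficient for PCE over batch, for TCE over batch and for the gene's dye effect, which left 3 residual degrees of freedom (prior degrees of freedom 3.28). The direct array entered as an independent array although it repeats RNA of cultures on other arrays, so these cultures weigh more. Part of the residual spread is therefore technical, and the standard errors, p-values and counts of calls rest on this. P-values were adjusted by Benjamini-Hochberg over the 1465 genes, with a threshold of 0.05. Values are log2 fold changes with moderated standard errors. Culture values are log ratios turned to culture over control and corrected for the fitted dye effect. The batch control entered as 1 RNA sample, so its own spread between cultures is left out. All arrays lie on 1 slide from 1 scan, so neither could be fitted as a block.

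The files pair no gene name or product with the locus IDs, and no annotation table was used here. Identities given for preset loci and gene lists (such as DET_0079 as tceA) are background knowledge of the published strain 195 locus numbering and were not checked against an annotation here. Lists planned by product text could not be matched that way. The reductive dehalogenases and the formate dehydrogenase-like complex were fixed by locus before the data were examined. Planned by product text were a single list of hydrogenases, the NADH-ubiquinone oxidoreductase-like (Nuo-like) complex, the ATP synthase and a wider nitrogen list that held nitrogenase. The split into Hup, Hym, Vhu, Ech and Hyc hydrogenases and a list of nitrogenase alone were not planned. Loci of these types, of all 5 together, of the Nuo-like complex, the ATP synthase and nitrogenase were written down after the IDs were seen. This was before any fold change was seen. The other planned lists were not analysed here. The rule for named genes, set beforehand, took per comparison the 8 largest rises and 8 largest falls past the threshold with the same sign on every array of the comparison, 16 preset loci, and up to 4 members of each list that passed. Other list members given with values (among them DET_0311, DET_1522, DET_0615, DET_0148, DET_0863, DET_1572 and DET_1576) were chosen after their values were seen. Genes without a known identity are given as counts and ranges, except 2 rising and 2 falling IDs. Lists were tested with camera (preset correlation 0.01), adjusted over the 11 lists of a comparison, with an estimated correlation and with fry as alternatives.

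The fit was tested on simulated data with the between-culture spread, dye effects and design of the real arrays, in 20 simulations with 200 changed genes per feeding among 1465. The spread was given to the continuous cultures only. The batch control had none and genes were drawn independently, so the shares of false calls leave out errors from both. For PCE against batch, 36.3% of changes of 0.5, 92.8% of changes of 1 and 100% of changes of 2 log2 units were recovered, and 3.6% of calls were false. For TCE against batch the shares were 39.3%, 93.3% and 99.9%, with 3.8% false calls. For TCE against PCE they were 11.2%, 62.6% and 98.1%, with 1.9% false calls. The number of arrays limits the precision.

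Alternatives covered the background, the normalisation, the filter, the probe summary, the dye term, the direct and self arrays, each culture left out, a replicate block, the authors' value table and a fold threshold. Added after seeing the data were a culture-level fit (self array subtracted, direct array left out, 2 residual degrees of freedom), that fit without each culture, a second assignment for the replicate block, and 2 further sets of arrays left out, also for the lists. The planned settings followed the feed rate in the labels of the direct array: leaving out PCE replicate 1 or TCE replicate 2 also left out the direct array, and leaving out TCE replicate 1 kept it. The further sets were TCE replicate 1 together with the direct array, and TCE replicate 2 with the direct array kept. In the same simulations the culture-level fit had 6.0%, 5.9% and 5.6% false calls for PCE against batch, TCE against batch and TCE against PCE, each a share above the threshold of 0.05.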

Results

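Transcript levels of Dehalococcoides ethenogenes strain 195, a bacterium that respires chlorinated ethenes with hydrogen, were compared between continuously fed and batch-fed subcultures of the Donna II mixed culture. The subcultures (100 mL) were fed tetrachloroethene (PCE) or trichloroethene (TCE) for 168 h, with 2 cultures per feeding. The feed rates were 10.6 and 7.3 µmol per L per h for PCE replicates 1 and 2, and 14.2 and 13.7 µmol per L per h for TCE replicates 1 and 2. The batch control had received 110 µmol per L PCE and was sampled after 6 h. Feeding mode was therefore tied to duration, and also to the electron donor to acceptor ratio, which was 2.75 to 4.54 in the continuous cultures and 15.7 in the batch control. On the 6 arrays, 81.8% to 94.2% of probe spots were well above background in Cy3 and 92.4% to 94.1% in Cy5, and no probe spot was saturated. PCE replicate 2 had the lowest share, in Cy3. Across genes, log ratios of the 2 PCE arrays correlated at 0.79 and those of the 2 TCE arrays at 0.90 (genes are not independent replicates), with SDs of the difference of 0.46 and 0.29. PCE culture 1 and TCE culture 1 correlated at 0.82 (SD 0.38), closer than the 2 PCE cultures to each other. All these values share the batch control.

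The first comparison asked how continuous PCE feeding differed from a batch dose. Under continuous PCE, genes of the ATP synthase and of the Ech hydrogenase, a membrane-bound energy-conserving type, were lower. Several reductive dehalogenase genes were higher, but as a list they did not pass. The PCE cultures had 245 genes higher and 254 lower than the batch control among 1465 tested (limma, Benjamini-Hochberg). Of these, 60 and 63 differed by at least 1 log2 unit.

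Reductive dehalogenases catalyse the removal of chlorine, and 14 of the 18 on the array were measured. In the PCE cultures 4 rose, 1 fell and 9 did not pass, where 34.1% of all genes tested were called. Adjusted over the list alone, 5 rose and 1 fell. The TCE dehalogenase gene tceA (DET_0079) was 1.67-fold higher (log2 0.74 ± 0.13 SE, adjusted p = 0.0104), with culture values of 0.74 ± 0.01 (SD, n = 2). The homologs DET_0180 (log2 1.89 ± 0.43, adjusted p = 0.0199), DET_1545 (1.34 ± 0.20, adjusted p = 0.00612) and DET_0311 (0.51 ± 0.11, adjusted p = 0.0155) also rose, and DET_1522 fell by 0.55 (± 0.13, adjusted p = 0.0224). The 2 cultures differed for DET_0180, at 1.26 and 2.81. The PCE dehalogenase gene pceA (DET_0318) had a log2 fold change of -0.11 ± 0.22 (adjusted p = 0.705), DET_1559 one of 1.14 ± 0.37 (adjusted p = 0.059) and DET_0173 one of 0.50 ± 0.29 (adjusted p = 0.23). DET_1559 passed as higher in 11 of 24 alternatives, among them median centring (adjusted p = 0.0355), no dye term (0.0101) and the culture-level fit (0.0226), and DET_0173 passed in 3. DET_1171 was too dim to be tested. As a list, the reductive dehalogenases did not pass (median log2 0.18, camera adjusted p = 0.0979), but did with Feature Extraction's processed signals (adjusted p = 0.0393), with median centring (0.033), without PCE replicate 1 and the direct array (0.0142) and without the control array of TCE replicate 1, the direct array kept (0.0492). With an estimated correlation its adjusted p = 0.647. Over 24 alternatives the log2 fold change of tceA ran from 0.51 to 1.33. The calls for tceA and DET_0180 were each kept in 18 of 24 alternatives. These counts include Aquantile normalisation between arrays and the median of probes, which could not move a value. That for tceA was lost with the processed signals (log2 0.53, adjusted p = 0.0569), with the authors' value table (0.54, adjusted p = 0.0503) and without the direct array (0.73, adjusted p = 0.142), and that for DET_0180 without the direct array (2.32, adjusted p = 0.0861) and without only the array of TCE replicate 2 (1.92, adjusted p = 0.087).

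Of the 8 ATP synthase genes, 6 fell and 2 did not pass (median -1.45, camera adjusted p = 0.00115, adjusted p = 0.647 with an estimated correlation). DET_0558 was 4.6-fold lower (log2 -2.20 ± 0.18, adjusted p = 0.00242), DET_0560 3.45-fold and DET_0561 3.17-fold. The last 2 loci of the run, DET_0564 and DET_0565, had values of -0.17 ± 0.17 and -0.12 ± 0.20. Of the 8 Ech genes, 7 fell (median -1.44, camera adjusted p = 0.00115, adjusted p = 0.647 with an estimated correlation). DET_0862 was 3.36-fold lower (log2 -1.75 ± 0.20, adjusted p = 0.00373) and DET_0861 3.1-fold, while DET_0863 stood at -0.04 ± 0.23. The calls of DET_0560, DET_0561, DET_0861 and DET_0862 were lost without the direct array (adjusted p from 0.0625 to 0.0646) and without the self array (0.0595 to 0.0648), at log2 values from -1.49 to -1.85. That of DET_0558 was lost without the self array (-2.07, adjusted p = 0.0595).

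The Nuo-like complex (11 genes) had 2 members that rose and 9 that did not pass (median 0.45, camera adjusted p = 0.00842, adjusted p = 0.743 with an estimated correlation). DET_0931 (0.95 ± 0.14, adjusted p = 0.00609) and DET_0929 (0.61 ± 0.11, adjusted p = 0.0104) were the ones that rose. Nitrogenase, the enzyme of nitrogen fixation, had 4 of 8 genes that rose (median 0.44, camera adjusted p = 0.00842, adjusted p = 0.647 with an estimated correlation), among them DET_1158 (0.73 ± 0.14, adjusted p = 0.0135) and DET_1157 (0.70 ± 0.13, adjusted p = 0.0113). Both list calls were lost without PCE replicate 1 and the direct array (adjusted p = 0.644 and 0.169), and without either TCE culture together with the direct array (adjusted p = 0.0534 for each). That of the Nuo-like complex was also lost without the direct array alone (adjusted p = 0.0538).

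Among the other hydrogenases, DET_0615 of the Vhu type rose 2.1-fold (log2 1.07 ± 0.14, adjusted p = 0.00522) and DET_1570 of the Hyc type rose by log2 0.53 ± 0.11 (adjusted p = 0.0178). No gene of the Hup hydrogenase (3 genes), the Hym hydrogenase (4) or the formate dehydrogenase-like complex (3) passed, and none of these lists nor Vhu, Hyc or all 25 hydrogenase genes together passed camera (adjusted p from 0.32 to 0.82). The preset loci of Hup, DET_0110 and DET_0112, each stood at log2 0.14 (± 0.46 and ± 0.29), with culture values of 0.88 and -0.84 for DET_0110. DET_0110 passed as lower without PCE replicate 1 and the direct array (-1.08, adjusted p = 0.00104) and as higher without PCE replicate 2 (0.56, adjusted p = 0.00975). All 25 hydrogenase genes together passed as lower without PCE replicate 1 and the direct array (median -0.57, adjusted p = 0.0142, against adjusted p = 0.82 with an estimated correlation on all arrays). The putative S-layer gene DET_1407 (-0.17 ± 0.17), the chaperonin gene groEL (DET_1428, -0.60 ± 0.31), DET_0145 of Hym (-0.43 ± 0.34), DET_0616 of Vhu (0.04 ± 0.16), DET_0187 (0.31 ± 0.17) and DET_1571 of Hyc (0.16 ± 0.16) did not pass, while DET_0865 of Ech fell by 1.40 (± 0.30, adjusted p = 0.0166). The 8 largest rises spanned log2 1.62 to 3.16 and included DET_0180, and the 8 largest falls spanned -1.63 to -2.20, 5 of them in the ATP synthase or Ech lists. The largest rise was that of DET_0298, for which the files give no name (8.97-fold, log2 3.16 ± 0.12, adjusted p = 0.000152). DET_1021, also unnamed, fell by 2.08 (± 0.42, adjusted p = 0.0142).

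The counts differed widely between settings. They were 6 and 1 without the direct array, 1 and 0 without the self array, 0 and 0 without TCE replicate 2 together with the direct array (limma, 227 genes at an unadjusted p under 0.05), 394 and 441 with no dye term, and 294 and 285 in the culture-level fit, which shared 472 of the 499 calls but had more false calls in simulations (6.0% against 3.6%). All 499 kept their direction without the direct array. That fit rests on the same cultures and control, so this is no separate evidence. Of 56 calls of named genes over the 3 comparisons, 19 were kept without the direct array and 21 without the self array.

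**Figure D1:**
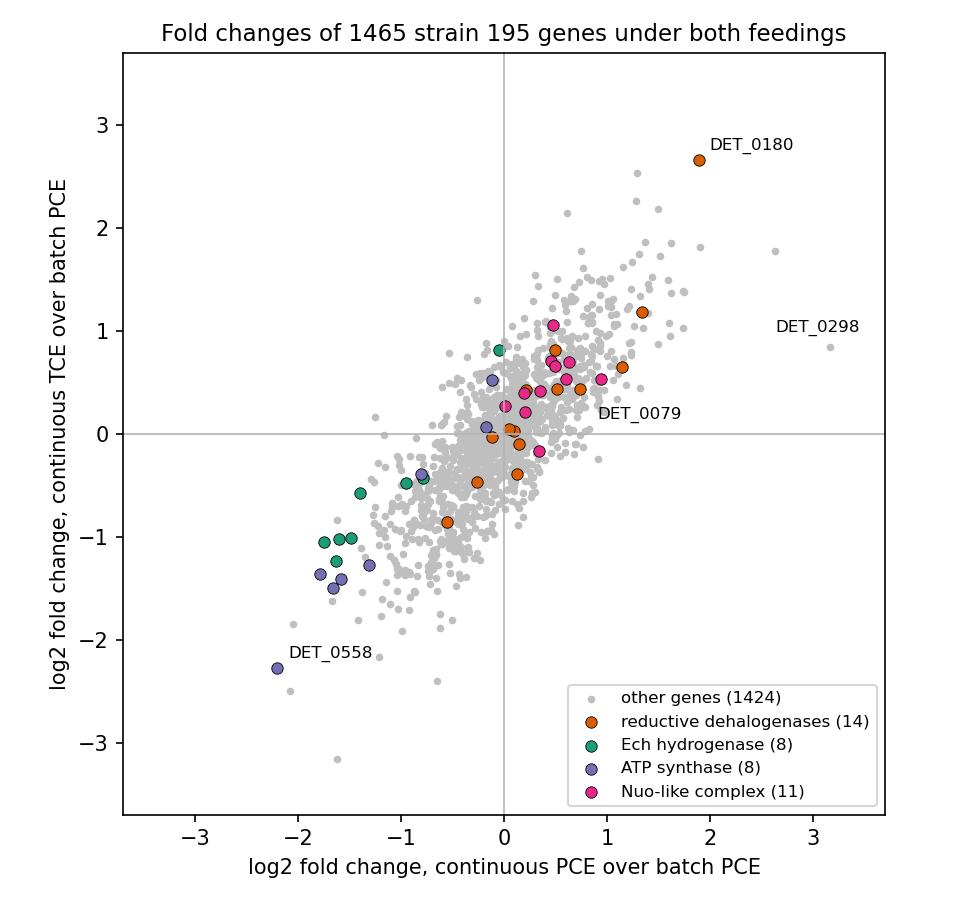
Each point is 1 of 1465 genes, with the log2 fold change of continuous PCE over batch PCE on the horizontal axis and of continuous TCE over batch PCE on the vertical axis, both from the limma fit. Coloured points are the reductive dehalogenases, the Ech hydrogenase, the ATP synthase and the Nuo-like complex. DET_0558 lies at -2.20 and -2.28, DET_0180 at 1.89 and 2.66, and DET_0298 stands apart at 3.16 and 0.85.

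The second comparison set continuous TCE feeding against the same batch PCE control, so the electron acceptor changed together with the feeding mode. Reductive dehalogenase DET_0180 was among the 8 largest rises past the threshold, ATP synthase genes were again lower, and genes of the Nuo-like complex were higher. In the TCE cultures 291 genes were higher and 329 lower than in the batch control, of which 88 and 111 differed by at least 1 log2 unit.

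Of the 14 measured reductive dehalogenases, 5 rose, 2 fell and 7 did not pass, where 42.3% of all genes tested were called. Adjusted over the list alone, 6 rose and 3 fell. DET_0180 was 6.3-fold higher (log2 2.66 ± 0.43, adjusted p = 0.00482), with culture values of 2.51 ± 0.12 (SD, n = 2). Its call was kept in 19 of 24 alternatives, counting Aquantile normalisation and the median of probes, which could not move a value. It was lost without the direct array (2.23, adjusted p = 0.0604) and in the culture-level fit without TCE replicate 1 (2.31) or 2 (2.14). DET_1545 was 2.27-fold higher (1.18 ± 0.20, adjusted p = 0.00584), and DET_1522 was lower by log2 -0.86 ± 0.13 (adjusted p = 0.004). For tceA the log2 fold change was 0.43 ± 0.13 (adjusted p = 0.043). Over 24 alternatives that value ran from 0.27 to 1.09. The tceA call was kept in 11 of 24 alternatives, again counting Aquantile normalisation and the median of probes. It was lost with the processed signals (adjusted p = 0.157), with the authors' value table (0.141) and without the direct array, alone (0.306) or together with PCE replicate 1 (0.134), TCE replicate 1 (0.47) or TCE replicate 2 (0.731). With the direct array kept, it was lost without the control array of TCE replicate 1 (0.0503) or of TCE replicate 2 (0.0541). Values that did not pass were -0.03 ± 0.22 for pceA, 0.65 ± 0.37 for DET_1559 and 0.82 ± 0.29 for DET_0173 (which passed in 3 and 7 of 24 alternatives). As a list the reductive dehalogenases did not pass (median 0.24, camera adjusted p = 0.455).

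Of the 8 ATP synthase genes, 5 fell (median -1.32, camera adjusted p = 0.0403, adjusted p = 0.815 with an estimated correlation). DET_0558 was 4.84-fold lower (log2 -2.28 ± 0.18, adjusted p = 0.00134), DET_0561 2.83-fold and DET_0562 2.43-fold, while DET_0565 stood at 0.53 ± 0.20. The list call was lost without PCE replicate 2 (adjusted p = 0.0966) and without TCE replicate 2, both together with the direct array (0.0856) and with that array kept (0.161). The Nuo-like complex had 5 of 11 genes that rose (median 0.54, camera adjusted p = 0.0403, adjusted p = 0.815 with an estimated correlation), led by DET_0932 (2.08-fold, log2 1.06 ± 0.16, adjusted p = 0.00376) and DET_0929 (0.54 ± 0.11, adjusted p = 0.0106). This call was lost with median centring (adjusted p = 0.108) and, with the direct array kept, without the control array of TCE replicate 1 (0.0625) or of TCE replicate 2 (0.0918).

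Of the 8 Ech genes, 4 fell, 1 rose and 3 did not pass. DET_0861 was 2.36-fold lower (log2 -1.24 ± 0.18, adjusted p = 0.00361) and DET_0863 was 1.76-fold higher (0.82 ± 0.23, adjusted p = 0.0311). The Ech list did not pass (median -0.79, camera adjusted p = 0.121) but did with no dye term (0.0417), without the direct array (0.0203), in the culture-level fit (0.0243), and without the direct array together with PCE replicate 1 (0.00594) or TCE replicate 1 (0.00201). With an estimated correlation its adjusted p = 0.815. Of the 7 Hyc genes, 3 rose and 2 fell, with DET_1572 at 1.35 ± 0.18 (adjusted p = 0.00294), DET_1571 at 0.72 ± 0.16 (adjusted p = 0.0123) and DET_1576 at -0.59 ± 0.11 (adjusted p = 0.00664). DET_0615 of Vhu rose 2.1-fold (1.07 ± 0.14, adjusted p = 0.0029) and DET_0148 of Hym rose 2.38-fold (1.25 ± 0.19, adjusted p = 0.00402). No Hup or formate dehydrogenase-like gene passed, and 2 of 8 nitrogenase genes rose (0 adjusted over the list alone). None of the lists of Hup, Hym, Vhu, Hyc, all hydrogenases, formate dehydrogenase-like or nitrogenase genes passed camera (adjusted p from 0.343 to 0.956). The S-layer gene DET_1407 rose 1.75-fold (0.81 ± 0.17, adjusted p = 0.0119). Preset loci that did not pass stood at 0.45 ± 0.31 for groEL, 0.54 ± 0.46 for DET_0110, -0.04 ± 0.29 for DET_0112, -0.06 ± 0.34 for DET_0145, 0.14 ± 0.17 for DET_0187, 0.21 ± 0.16 for DET_0616 and -0.58 ± 0.30 for DET_0865. The 8 largest rises spanned 1.82 to 2.66 and the 8 largest falls -1.85 to -3.16. The largest among loci without a known name were DET_1051 (5.79-fold higher, log2 2.53 ± 0.16, adjusted p = 0.000751) and DET_1511 (8.93-fold lower, log2 -3.16 ± 0.48, adjusted p = 0.00391). DET_1021 fell by 2.50 (± 0.42, adjusted p = 0.00513).

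Counts were 49 and 58 without the direct array, 85 and 105 without the self array, 0 and 0 without TCE replicate 2 together with the direct array (limma, 230 genes at an unadjusted p under 0.05), and 271 and 338 in the culture-level fit, which shared 552 of the 620 calls (false calls in simulations 5.9% against 3.8%). All 620 kept their direction without the direct array, again in a fit on the same cultures and control.

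**Figure D2:**
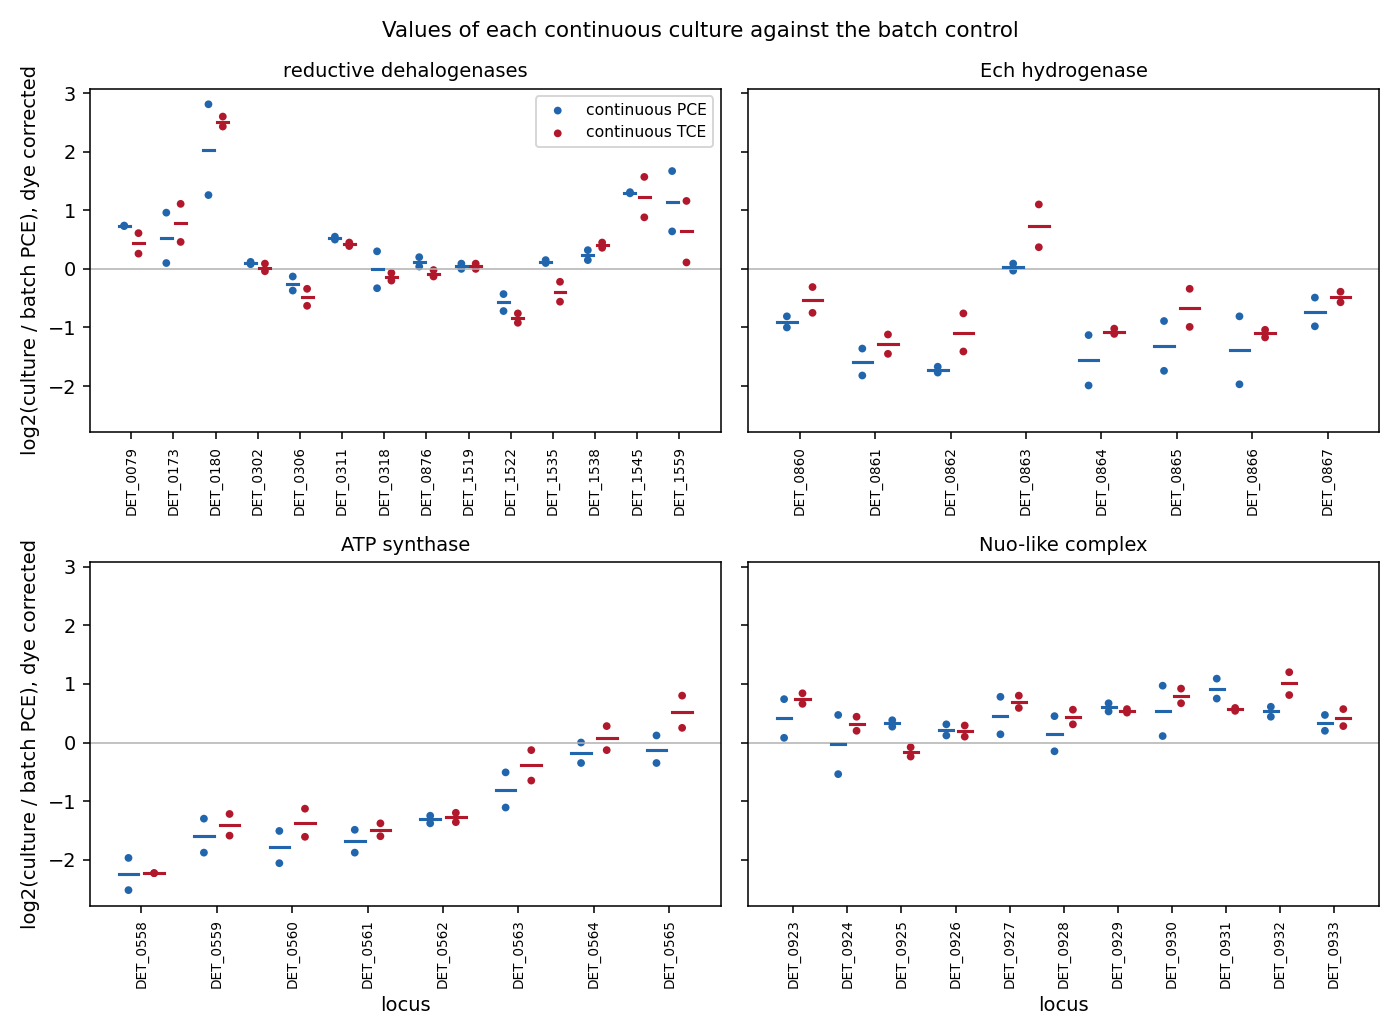
Points are single cultures, given as log2 of culture over batch PCE after correction for the fitted dye effect, and short lines are the mean of the 2 cultures of a feeding, PCE in blue and TCE in red. DET_0558 to DET_0562 of the ATP synthase lie below 0 in all 4 cultures, and DET_0863 is the Ech gene with TCE values above 0.

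The fold changes of the 2 feedings ran together. Of the calls, 167 genes were higher and 185 lower in both, and 2 went in opposite directions. Independent lists of these sizes would share 48.7 and 57 genes. The correlation across genes was 0.79 and 80.5% of genes had the same sign. Unchanged cultures simulated against 1 shared control that varied as the continuous cultures did gave a correlation of 0.67 and 73.4%. The covariance was 0.308, against 0.055 in those simulations. The single control could not be split, so part of the excess may come from it. Shared calls fell to 3 and 1 without the direct array and rose to 288 and 333 with no dye term.

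The third comparison set continuous TCE against continuous PCE. DET_0298 was the gene that differed, 4.99-fold lower under TCE (log2 -2.32 ± 0.19, 95% confidence interval -2.79 to -1.85, adjusted p = 0.0213). Its values over batch were 3.12 and 3.28 in the PCE cultures and 0.81 in each TCE culture. No gene passed as higher (limma), and 78 were higher and 96 lower at an unadjusted p under 0.05, where 73 in all would be expected by chance. The call was lost without the direct array (adjusted p = 0.788), without the self array (1), without the control array of TCE replicate 1 (0.0789) or of TCE replicate 2 (0.238) with the direct array kept, without TCE replicate 2 and the direct array (0.998) and with the authors' value table (0.0603). Over all 24 alternatives the value ran from -2.61 to -1.98, and 14 of them kept the call. Aquantile normalisation between arrays and the median of probes, which could not move a value, are counted among the 14. With no dye term 99 genes were higher and 149 lower. That difference also holds the gene's dye effect, because PCE cultures were always in Cy3 and TCE cultures in Cy5.

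None of the 14 reductive dehalogenases differed between the feedings past the threshold. The interval of the log2 difference was -0.84 to 0.22 for tceA, -0.80 to 0.97 for pceA and -0.93 to 2.46 for DET_0180. The sign of the difference was kept in 15 of 24 alternatives for DET_0180 and in 13 for pceA. Aquantile normalisation and the median of probes are counted among these. For DET_0180 the sign turned when only the direct array was left out. In the culture-level fit without PCE replicate 1 the difference of DET_0180 stood at -0.87 and that of pceA at -0.84. The S-layer gene DET_1407 was 0.98 ± 0.28 higher under TCE (unadjusted p = 0.0123, adjusted p = 0.373) and groEL 1.05 ± 0.51 higher (adjusted p = 0.448), neither past the threshold. As a list, the Ech genes were less reduced under TCE (median difference 0.53, camera adjusted p = 0.0173, adjusted p = 0.809 with an estimated correlation), although no single member passed. All 25 hydrogenase genes together were higher under TCE (median 0.37, camera adjusted p = 0.0203, adjusted p = 0.809 with an estimated correlation), again with no member past the threshold. The Ech call was lost without the direct array, alone (median 0.24, adjusted p = 0.221) or together with PCE replicate 1 (-0.12, adjusted p = 0.95) or TCE replicate 1 (-0.03, adjusted p = 0.698), and in the culture-level fit (0.24, adjusted p = 0.186). That of all hydrogenases was lost without TCE replicate 1 and the direct array (0.23, adjusted p = 0.0669). No other list passed (adjusted p from 0.151 to 0.87). Without PCE replicate 1 and the direct array the lists of Hup (median 1.35, adjusted p = 0.000634), Hym (1.22, adjusted p = 0.000983), ATP synthase (0.49, adjusted p = 0.0198) and Nuo-like genes (0.27, adjusted p = 0.0379) passed as higher under TCE. On all arrays with an estimated correlation, their adjusted p was 0.809 for Hym and ATP synthase and 0.93 for Hup and Nuo-like genes. Over 14 alternatives, Hym passed in 5 and ATP synthase in 4.

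With the batch control on both channels, log ratios had an SD of 0.163 over the 1465 genes, with the 5th and 95th percentiles at -0.24 and 0.25. Of these genes, 14 exceeded 0.5 log2 units and 2 exceeded 1. For genes named above, the self array gave 0.30 for tceA and for DET_0298, both beyond the 95th percentile. The same array gave -0.13 for DET_0180, 0.05 for DET_0558 and -0.08 for DET_0862. It gave -0.47 for DET_1051, beyond the 5th percentile, and 0.24 for DET_1511.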

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

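The tests of a faulty probe and of a single deviating culture, and those of the probes without a strain 195 locus ID, were chosen after the results were seen.

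DET_0298 stood out because its response to the 2 continuous feedings differed in a test of the difference itself, with a log2 fold change of TCE against PCE of -2.32. A fault of its own probe would not move its neighbour. A neighbour can also change or stay unchanged on its own account, so its value can neither show nor exclude such a fault. The locus numbered 1 below, measured by a different probe, had a value in the same direction (-0.86, interval -1.71 to -0.01, adjusted p = 0.414), which did not pass. The lowest PCE culture lay 2.31 log2 units above the highest TCE culture, so the difference did not rest on 1 culture. DET_0298 was picked as the gene with the smallest adjusted p in this comparison. Such a gap was therefore bound to be found and is no separate evidence. The electron acceptor, the feed rate, the respiration rate and the donor to acceptor ratio (3.12 and 4.54 under PCE, 2.75 and 2.84 under TCE) all differ between the feedings, and which of them the difference may follow was not tested.

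Probes without a strain 195 locus ID gave signal outside the main measurement, with 40.1% of their spots well above background over both channels against 2.06% of negative control spots and 94.3% of strain 195 spots. Of 144 such probes 74 passed the filter. In PCE cultures 17 were higher and 15 lower than in the batch control, and in TCE cultures 16 were higher and 20 lower (limma, adjusted over these probes). Of the 6 measured probes whose names end in MHU, all 6 rose under PCE (log2 1.24 to 2.96), and 5 rose under TCE, with the remaining probe at -0.30. The files do not state their organism, and these values are relative to strain 195 transcripts.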

How the results depend on the processing

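The culture-level fit, the other assignment of the replicate block and the further sets of arrays left out were chosen after seeing the data, as were list tests under median centring, the culture-level fit, the block and left-out cultures. Counts below are higher then lower, for PCE against batch, TCE against batch and TCE against PCE, where the values above were 245 and 254, 291 and 329, and 0 and 1. Median centring, loess on all probes and both filters kept every count within 1.5 times, as did the processed signals and the authors' value table except for TCE against PCE (2 lower and 0 lower). Aquantile and the median of probes cannot move these values and tested nothing. With no dye term the counts were 394 and 441 for PCE and 99 and 149 for TCE against PCE. In that setting every fold change also holds the gene's dye effect, because each feeding was hybridised in 1 dye orientation only. Without the direct array they were 6 and 1, 49 and 58, and 0 lower, and without the self array 1 and 0, 85 and 105, and 0 lower, with 2 residual degrees of freedom left. A fold threshold of 1 log2 unit gave 60 and 63, and 88 and 111. Without each culture in turn, over both kinds of fit, counts ranged from 0 to 365 and 0 to 377, 0 to 424 and 0 to 466, and 0 to 209 and 0 to 256; against batch, the 0s come with 1 residual degree of freedom, without either TCE culture together with the direct array, and the lone culture is taken to vary like the others. The labels do not say that the numbers of the titles pair the cultures, and 2 pairs, whose deviations correlated at 0.36, leave it undecided. With the replicate block TCE against PCE gave 4 and 8, and with the direct array taken as TCE culture 1 it gave 0 lower, while the block kept the other counts within 1.5 times. Under the block the tceA call against batch was lost for TCE (adjusted p = 0.237), as were the list calls of ATP synthase for TCE (0.0959) and of Ech between feedings (0.103). Of 56 named calls, 0 were kept without either TCE culture together with the direct array, 19 without the direct array, 21 without the self array, 53 with the processed signals, 55 under the block and 56 in the culture-level fit, which had more false calls in simulations (5.6% to 6.0%). That fit kept 25 without TCE replicate 1 and 36 without TCE replicate 2. Of 8 list calls, 8 were kept with the processed signals, 7 in the culture-level fit, 6 under the block, 4 without TCE replicate 1 and the direct array, 2 with fry and 0 with an estimated correlation. The last setting had little power. There nitrogenase under PCE went from an unadjusted camera p = 0.00304 to 0.0779, although its estimated correlation was only 0.05. Under the block as first assigned DET_1559 and DET_0173 passed under PCE (adjusted p = 0.000932 and 0.0218). With the direct array taken as TCE culture 1, the block kept 51 of the 56 named calls, and that of DET_0180 under PCE was lost (1.46, adjusted p = 0.0674). Without PCE replicate 1 and the direct array, directions turned for DET_0110 under PCE (range over left-out cultures -1.08 to 0.64) and for the Ech list between feedings (-0.12 to 0.53), and without PCE replicate 1 in the culture-level fit for DET_0318 (-0.29 to 0.50 under PCE, -0.84 to 0.08 between feedings), DET_0112 (-0.57 to 0.49 and -0.35 to 0.71) and DET_0180 (-0.87 to 0.77 between feedings). The direction of DET_0180 between feedings also turned when only the direct array was left out. The fit without the direct array and the culture-level fit both leave that array out and have 2 residual degrees of freedom. They gave the same fold changes (median over genes -0.004 for PCE and -0.027 for TCE against batch in both). The culture-level fit carries no error of the self array, which sets their counts apart (6 and 1 against 294 and 285 for PCE). Beyond the dye effect held in fold changes with no dye term, the cause of the other changes, of the other counts included, was not tested. The SD of the self array was 0.231 with processed signals and 0.277 with median centring. Genes higher and lower in both feedings were 288 and 333 with no dye term and 3 and 1 without the direct array. No second slide or scan could be fitted as a block. The share of spots well above background was lowest in Cy3 of PCE replicate 2 (81.8%).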

Other observations

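The comparisons between cultures of 1 feeding, the tests on adjacent loci and on runs of 8 loci, and those of dye bias, of the batch control and of the direct array's culture were chosen after the results were seen.

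In PCE culture 2, fed at the lower rate (7.3 against 10.6 µmol per L per h), the 3 Hup genes had a median of -0.51 over batch, against 0.88 in culture 1 (median difference -1.50). The 4 Hym genes (median difference -0.75) and the 8 ATP synthase genes (-0.51) also had lower values in culture 2, and none of the 8 Ech genes did (0.48). Deviations from the fit were shared within a complex (estimated correlations of 0.99 for Hup, 0.94 for Hym, 0.91 for ATP synthase and 0.76 for Ech), so its genes are not independent values. The array of PCE replicate 2 also had the lowest share of spots well above background (81.8% in Cy3) and the highest share of outlier spots (4.06%). Between the TCE cultures, fed at 14.2 and 13.7 µmol per L per h, the median difference of culture 2 from culture 1 was -0.15 for Hup, -0.33 for Hym, -0.39 for Ech, -0.40 for ATP synthase and -0.22 for all 25 hydrogenase genes. Each of these is 1 culture against another and has no replicate check.

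Loci with adjacent numbers changed together. Across 1386 adjacent pairs the fold changes correlated at 0.48 for PCE against batch, 0.35 for TCE against batch and 0.22 for TCE against PCE, against at most 0.09, 0.11 and 0.08 in 2000 permutations of the locus order (p = 5e-04, the smallest these can give). The run of 8 measured loci with the lowest median under PCE (-1.45, 7 of them called, lowest of 1000 permutations -1.06) held the ATP synthase genes DET_0558 to DET_0562. Under TCE a run of 8 loci elsewhere had the lowest median (-1.37, all 8 called), where the lowest of the permutations was -1.28. The runs with the highest medians (1.16 and 1.00) did not exceed the highest of the permutations (1.26 and 1.43).

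Many genes changed the same way under both feedings. Dye bias as the whole cause is argued against, because the feedings were hybridised in opposite orientations and their fold changes correlated at 0.83 with no dye term, where a dye effect alone gives a negative value. A chance deviation of the single batch control could have added to the pattern. The observed covariance exceeded the simulated one by 0.253, but the spread between batch cultures was not measured, so this cannot be told apart from the effect of feeding. Duration and donor ratio differ from the control in every continuous culture and stay open too.

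The labels of the direct array name the feed rate (13.7 µmol per L per h) and respiration rate (81.6 µeeq per L per h) of TCE replicate 2 but the donor ratio of TCE replicate 1 (2.75). Calculated from PCE replicate 1, TCE replicate 1 and the self array, its log ratios were met with an SD of 0.090 over genes (r = 0.97). With TCE replicate 2 the SD was 0.287 (r = 0.65). This is consistent with RNA of TCE replicate 1 on the direct array and argues against TCE replicate 2. With PCE replicate 2 in place of replicate 1 the SD was 0.460 or 0.436, so the scanner files, and not the exchanged columns of the deposited value table, match the label that puts the 10.6 µmol per L per h culture on that array.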
